A study of Homo sapiens with 22 samples.

How the data were processed

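RNA from 22 human samples had been hybridised to one-colour short-oligonucleotide arrays. The 1 table used here holds 12624 probe sets, 67 of them array controls, and the deposited values are signal intensities on a linear scale with 1 decimal, as the values themselves show (0 missing, 7 equal to 0). The software that made the intensity values, its background step and its normalization are not given in the sources used here. The values show that the authors scaled each array to a common level, since the mean without the top and bottom 2% of the values was the same within 5% in each of 2 sets of arrays. It was 500.3 in a set of 9 arrays (the 4 Caco-2 arrays and duodenum 1 to 5) and 241.5 in a set of 13 arrays (duodenum 6 to 10 and the other tissue arrays). As the sets follow sample type in part and duodenum spans both, deposited values cannot be compared across them or show whether a gene differs.

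The 6 groups were taken from the source label of each sample, and array numbers from the titles. Intensities were quantile normalized over all arrays, values under the pooled 20th percentile (27.67, or 4.79 on the log2 scale) were raised to it, and log2 was taken. Probe sets above the pooled 40th percentile (78.62) on at least 2 arrays were kept, 9123 in all. Quantile normalization assumes a like distribution of levels in every sample, so a change shared by most genes would not be seen. Gene names came from the platform annotation, in which 10941 probe sets have 1 symbol, 546 have several and 1070 have none, and 0 symbols were updated through gene numbers. Only probe sets with 1 symbol were used. The probe set with the highest mean stood for a gene, a rule that mattered for 1468 of the 7167 genes tested. Between 0 and 16 genes per comparison had probe sets called in opposite directions. Left out were 20 probe sets of sex-linked genes or of genes with common deletions, which could tell about a person.

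The 8 comparisons were fitted in a single model of the 6 groups over all 22 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual degrees of freedom), so that groups of 2 arrays shared an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison, and candidate enzymes were also tested over all groups with the moderated F test. In total 35 gene lists were fixed, of enzymes, transporters, cell type markers and pathways, and the 34 with at least 4 measured genes were tested with camera, at a preset correlation of 0.01 and again with an estimated one. Figures and permutation tests were made with R or Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The groups, lists, comparisons, tests, most alternatives and the rule for naming genes were chosen before the data were examined. By that rule the text names, among called genes whose arrays did not overlap between the groups, the 6 or 4 with the largest difference each way, the phosphorylases and glycosylases given first, and up to 4 members with the largest difference of each list described. Lists described are those of nucleoside enzymes, P450 enzymes and transporters, and those with a camera adjusted p under 0.05. AFP, ACTA2 and other genes can belong to more than 1 list or part of the rule, as LYZ does to Paneth and myeloid cells.

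Changes were simulated on real genes. A planted change of 2 on the log2 scale was recovered for 37.1% of genes in Caco-2 day 16 against day 4, 65.7% in day 16 and 57.7% in day 4 against duodenum, 48% in day 16 against colon, 62.2% in jejunum, 61.6% in ileum and 71.4% in colon against duodenum, and 60% in colon against ileum. A change of 1 was recovered for 2.02% to 29.9%, so many may be missed. Fewer genes changed than in most comparisons, so real rates may differ. Ileum and colon arrays of the same number deviated together from their group means (correlations from 0.426 to 0.637 across genes, against at most 0.362 for arrays of different numbers, whose mean of -0.216 is negative by construction), which is a hint from the data, as the labels name no shared donor. With the number as a block, colon against ileum gave 93 genes in place of 15.

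Alternatives were no scaling, floors at the 10th and 40th percentile, no filter or a filter at the 60th percentile, the mean of a gene's probe sets, only the arrays of the 2 groups, array weights, eBayes with trend and robust settings, a fold of at least 2, the array number as a block, Pearson correlation, and each array left out in turn. After seeing the data 4 more were added, which were scaling to a common trimmed mean, the scaling set as a block, only duodenum arrays of the same scaling set, and leaving out ileum 3 and colon 3.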

Results

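RNA levels in human intestine and Caco-2 cells were measured on 22 arrays. Caco-2 is a human colon carcinoma line that forms an enterocyte-like layer and is used as a model of drug absorption. It was sampled 4 days (n = 2) and 16 days (n = 2) after seeding. Tissue RNA came from duodenum (n = 10), jejunum (n = 2), ileum (n = 3) and colon (n = 3). The series set out to find enzymes that act on nucleoside analogs, a class of antiviral and anticancer drugs. The array medians ran from 151 to 224 in the 9 arrays of one scaling set and from 73.8 to 93.5 in the 13 arrays of the other. Differences between groups are given on the log2 scale with their standard error, and the number of arrays limits their precision. Where every array of the dimmer group lay at the floor of the scale, only a bound is given, as a fold change of at least that size. Where all of them lay less than 2-fold above the floor, the difference is a limit too, written as "or more" or "or lower". Nothing in the labels says that the arrays of a group came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical.

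Candidate nucleoside-cleaving enzymes came first. Tissue groups differed in muscle and brush border genes, so their enzyme differences may not be regional. The nucleoside phosphorylases TYMP (thymidine phosphorylase) and UPP1 (uridine phosphorylase) were lower in Caco-2 cells than in duodenum, and PNP (purine nucleoside phosphorylase) was lower in jejunum, ileum and colon than in duodenum. The mean log2 level of TYMP was 4.89 ± 0.15 (SD, n = 2) on day 4 and 4.91 ± 0.10 (n = 2) on day 16, close to the floor at 4.79, and 9.51 ± 0.41 (n = 10) in duodenum. The difference from duodenum was -4.61 ± 0.46 or lower on day 4 (adjusted p = 2.11e-07) and -4.59 ± 0.46 or lower on day 16 (adjusted p = 2.92e-07), and the difference of day 16 from colon was -3.41 ± 0.54 or lower (adjusted p = 9.14e-05). UPP1 had a mean of 7.86 ± 0.53 on day 4, 5.61 ± 1.16 on day 16 and 9.12 ± 0.33 in duodenum. It fell by 2.25 ± 0.46 between the Caco-2 time points (adjusted p = 0.0143) and lay below duodenum by -3.51 ± 0.35 on day 16 (adjusted p = 2.92e-07) and by -1.26 ± 0.35 on day 4 (adjusted p = 0.00885). The fall of UPP1 no longer passed without array 1 of day 4 (adjusted p = 0.0748) or without array 2 of day 16 (-1.43, adjusted p = 0.294). The day 4 difference from duodenum no longer passed without array 2 of day 4 (adjusted p = 0.209), against the 5 duodenum arrays of the same scaling set (adjusted p = 0.0839) or on deposited values (adjusted p = 0.338). PNP had its highest mean in duodenum, 10.39 ± 0.45, and differed from it by -1.84 ± 0.40 in jejunum (adjusted p = 0.00149), -1.06 ± 0.34 in ileum (adjusted p = 0.025) and -1.96 ± 0.34 in colon (adjusted p = 0.000203). Its jejunum difference no longer passed without jejunum 2 (adjusted p = 0.0888), and its ileum difference no longer passed without ileum 1 (adjusted p = 0.0654), without ileum 2 (adjusted p = 0.146) or with the scaling set as a block (adjusted p = 0.0799). In Caco-2 cells PNP differed from duodenum by -0.91 ± 0.40 on day 16 (adjusted p = 0.111) and -0.98 ± 0.40 on day 4 (adjusted p = 0.0727), which did not pass. TYMP was below duodenum in colon by -1.18 ± 0.39 (adjusted p = 0.0265), a call that ended without colon 1 (adjusted p = 0.139), without colon 2 (adjusted p = 0.225) and against the duodenum arrays of the same scaling set (adjusted p = 0.0581).

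DNA glycosylases remove damaged or mispaired bases from DNA. NTHL1, which removes oxidised pyrimidines, and MPG, which removes alkylated purines, were higher in jejunum, ileum and colon than in duodenum. NTHL1 was higher by 2.43 ± 0.43 in jejunum (adjusted p = 0.000228), by 1.71 ± 0.36 in ileum (adjusted p = 0.00164) and by 2.21 ± 0.36 in colon (adjusted p = 0.000104). In Caco-2 cells it was higher by 2.38 ± 0.43 on day 4 (adjusted p = 0.000211) and 1.56 ± 0.43 on day 16 (adjusted p = 0.0101). The Caco-2 day 16 call of NTHL1 ended without either day 16 array, and its ileum call ended on deposited values. MPG had a mean of 7.63 ± 0.60 (n = 10) in duodenum and was higher by 2.04 ± 0.43 in jejunum (adjusted p = 0.00108), 1.18 ± 0.36 in ileum (adjusted p = 0.0197) and 1.23 ± 0.36 in colon (adjusted p = 0.0138). With the scaling set as a block the MPG difference was 0.84 in ileum (adjusted p = 0.115) and 0.90 in colon (adjusted p = 0.0879), and neither passed. The ileum call of MPG also ended without ileum 1 (adjusted p = 0.124) or ileum 2 (adjusted p = 0.135), and the colon call without colon 1 (adjusted p = 0.105) or colon 2 (adjusted p = 0.0677). OGG1, which removes 8-oxoguanine, had means from 8.21 in colon to 9.06 in jejunum and passed in none of the 8 comparisons. With the mean of its probe sets its difference between day 4 and duodenum turned from 0.08 to -1.03 and passed (adjusted p = 0.0146). In Caco-2 cells MPG differed from duodenum by 1.06 ± 0.43 on day 16 (adjusted p = 0.0776) and 0.32 ± 0.43 on day 4 (adjusted p = 0.626). Over the 6 groups together, 8 of the 10 measured candidates differed in limma's moderated F test, 5 of the 7 glycosylases and 3 of the 3 phosphorylases, and the same number passed when adjusted over the list alone, beside 4106 of the 7167 genes. The adjusted p was 1.93e-05 for NTHL1, 0.00218 for MPG and 0.163 for OGG1, and for the phosphorylases 8.23e-08 for TYMP, 2.44e-06 for UPP1 and 0.000411 for PNP. MTAP (methylthioadenosine phosphorylase) lay below the filter on dim probe sets and was not tested. The 7 glycosylases did not shift as a set in any comparison, with adjusted p from 0.229 to 0.879, and the 3 phosphorylases were too few for a set test.

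**Figure D1:**
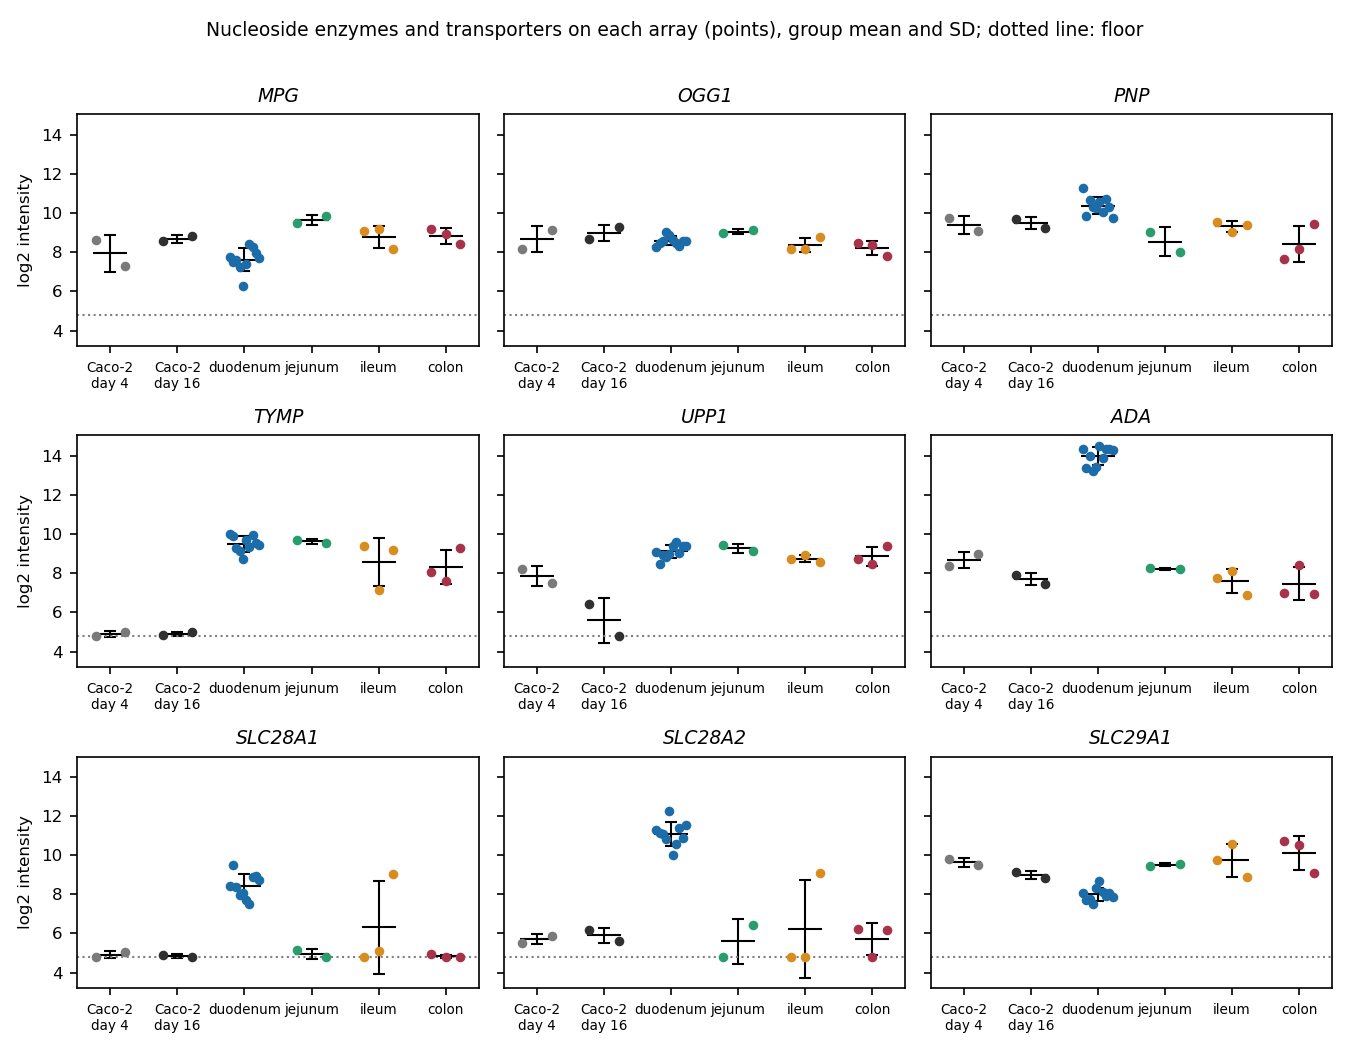
Log2 normalised intensity (vertical axis) of 9 genes of nucleoside metabolism and transport in the 6 groups (horizontal axis), with 1 point per array, the group mean and its SD, and a dotted line at the floor. TYMP lies near the floor at 4.79 on the Caco-2 arrays and ADA has a mean of 13.99 on the 10 duodenum arrays.

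Caco-2 cells 16 days after seeding were set against duodenum, where oral drugs first meet the absorbing epithelium. Most measured plasma proteins that the liver normally makes were higher in the cells, and P450 enzymes were lower as a set. Most measured genes of the brush border, of Paneth cells and of B and plasma cells were lower, but these 3 lists did not pass with an estimated correlation (adjusted p from 0.102 to 0.185). AFP, the fetal counterpart of albumin, was at least 534-fold higher (adjusted p = 1.84e-15), as were the fibrinogen chains FGB, at least 162-fold (adjusted p = 2.33e-17), and FGG, at least 155-fold (adjusted p = 1.01e-16). ALB (albumin) was higher by 7.93 ± 0.38 or more, the cell-surface proteoglycan GPC3 by 7.83 ± 0.67 and the plasma glycoprotein AHSG by 7.56 ± 0.54, with adjusted p of at most 2.83e-08. The Paneth cell defensin DEFA5 differed by -9.45 ± 0.77 or lower, the immunoglobulin chains IGLC1 and IGHM by -9.25 ± 0.83 or lower and -9.00 ± 0.90, the secreted lectin-like protein REG1A by -8.76 ± 0.95 and the chylomicron protein APOA4 by -8.46 ± 1.14, with adjusted p of at most 1.27e-05. A second defensin, DEFA6, was at least 445-fold lower (adjusted p = 9.01e-06).

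Among the 23 nucleoside kinases, deaminases and nucleotidases, which activate or inactivate nucleosides, 4 were higher and 6 lower (5 and 6 adjusted over the list alone), and the set did not shift (adjusted p = 0.236). ADA, which deaminates adenosine, differed by -6.29 ± 0.40 (adjusted p = 3.66e-10), and XDH, which oxidises purine bases, by -2.83 ± 0.68 (adjusted p = 0.00405). DPYD, the first enzyme of pyrimidine breakdown, was at least 9.11-fold lower (adjusted p = 3.64e-05), and AHCY, which hydrolyses S-adenosylhomocysteine, was higher by 2.77 ± 0.27 (adjusted p = 1.78e-07). Of the 4 nucleoside transporters 2 were lower (2 higher and 2 lower adjusted over the list alone; adjusted p = 0.284 for the set). The concentrative transporters SLC28A2 and SLC28A1 differed by -5.19 ± 0.76 and -3.55 ± 0.68 or lower (adjusted p = 3.52e-05 and 0.000569), while the equilibrative SLC29A1 had a difference of 0.99 ± 0.39 that did not pass (adjusted p = 0.0695). Of the 22 cytochrome P450 enzymes 7 were lower and none higher, also when adjusted over the list alone (adjusted p = 0.00296, adjusted p = 0.0256 with an estimated correlation). CYP3A4, the main drug-oxidising P450 of the gut, differed by -7.58 ± 1.17 (adjusted p = 6.13e-05), CYP2J2 by -5.50 ± 1.06, CYP3A5 by -4.17 ± 0.60 and CYP4F2 by -3.88 ± 0.87, with adjusted p of at most 0.00244. Of the 21 conjugating enzymes and esterases 3 were higher and 5 lower (3 and 7 adjusted over the list alone; adjusted p = 0.0288, adjusted p = 0.321 with an estimated correlation). The carboxylesterase CES2 was at -4.53 ± 1.02 and the glucuronosyltransferase UGT2B7 at -3.46 ± 0.95. Of the 19 drug and organic solute transporters 1 was higher and 6 lower (1 and 8 adjusted over the list alone; adjusted p = 0.0466, adjusted p = 0.294 with an estimated correlation). The peptide transporter SLC15A1 was at -3.32 ± 0.87, the efflux pumps ABCG2 at -3.00 ± 0.88 and ABCB1 at -2.35 ± 0.79, and the organic anion transporter SLCO2B1 at 2.56 ± 0.61. This set no longer passed with the scaling set as a block (adjusted p = 0.057) or against same-set duodenum arrays (adjusted p = 0.0584). The 19 amino acid and sugar transporters held 6 higher and 4 lower members in both adjustments, did not shift (adjusted p = 0.366), and had a median of 0.55 and a mean of -0.04. The sodium-glucose transporter SLC5A1 was at -7.97 ± 1.08 or lower and the neuronal-type glucose transporter SLC2A3, which is also on the hypoxia list, at 4.40 ± 0.61.

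The hepatocyte secreted proteins were higher in 18 of 24 members (19 adjusted over the list alone; adjusted p = 4.84e-23, adjusted p = 2.03e-05 with an estimated correlation). Cholesterol synthesis genes were higher in 11 of 15 (13 adjusted over the list alone; adjusted p = 6.64e-08, adjusted p = 0.0256 with an estimated correlation), with MVD higher by 3.93 ± 0.36 and HMGCS1 by 3.19 ± 0.37. Cell cycle genes were higher in 19 of 49 (23 adjusted over the list alone; adjusted p = 4.44e-07, adjusted p = 0.167 with an estimated correlation). UBE2C, which marks mitotic proteins for breakdown, was at 3.68 ± 0.69. Brush border hydrolases were lower in 12 of 15 in both adjustments (adjusted p = 1.54e-08, adjusted p = 0.167 with an estimated correlation). The peptidase MEP1B was at -6.72. MHC class II genes were lower in 7 of 10 (8 adjusted over the list alone; adjusted p = 1.03e-09), with HLA-DRA at -7.13 ± 0.45. Interferon response genes were lower in 19 and higher in 2 of 29 (20 and 2 adjusted over the list alone; adjusted p = 5.55e-09), with IFI27 at -5.74 ± 0.53 or lower. Enteroendocrine genes were lower in 6 of 13 (7 adjusted over the list alone; adjusted p = 2.78e-06). The hormone gene SST was at least 115-fold lower. For each of these 3 lists the adjusted p was 0.0256 with an estimated correlation. Lipid absorption and apolipoprotein genes, 5 lower and 3 higher of 14, did not shift (adjusted p = 0.113). Several lists of cell types that tissue holds and a pure culture lacks had lower members too, but not enteric neurons and glia, with 1 of 18 lower (adjusted p = 0.275), or mast cells, with 0 of 4 (adjusted p = 0.858). Smooth muscle genes were lower in 12 of 17 (adjusted p = 1.21e-09, adjusted p = 0.128 with an estimated correlation). The actin gene ACTA2 was at least 122-fold lower. B and plasma cell genes were lower in 9 of 17 (adjusted p = 3.3e-05, adjusted p = 0.185 with an estimated correlation), and Paneth cell genes in 7 of 8 (adjusted p = 5.06e-07, adjusted p = 0.102 with an estimated correlation). These 6 counts were the same adjusted over the list alone. Fibroblast and matrix genes were lower in 14 and higher in 4 of 28, immediate early genes lower in 10 and higher in 1 of 35 (11 and 1 adjusted over the list alone). Members were lower in 10 of 23 T and NK cell genes, 7 of 19 myeloid genes, 6 of 12 endothelial genes, 6 of 8 metallothioneins, 5 of 21 colon epithelium genes, 3 of 10 gastric gland genes and 1 of 4 red blood cell genes (11, 8, 7, 7, 6, 4 and 1 adjusted over the list alone). These 9 lists had adjusted p from 1.28e-05 to 0.0448, and adjusted p from 0.0878 to 0.399 with an estimated correlation. Of the 34 lists tested, 22 passed, and 6 passed with an estimated correlation. In all, 1773 of 7167 genes differed, 964 higher and 809 lower in the cells. With the scaling set as a block the count was 1498 (826 higher, 672 lower), and against the 5 duodenum arrays of the same scaling set it was 1202 (667 higher, 535 lower). The share of calls that were higher was 54.4% after quantile normalization and 78.3% on deposited values, where the median of all genes lay 0.58 higher in the cells. The unlike scaling of the sets can give such a shift. Without array 1 of day 16 the count was 1053, and without array 2 it was 862. Without array 1 the calls of ABCB1, ABCG2, NTHL1, SLCO2B1 and UGT2B7 ended (adjusted p from 0.0653 to 0.184), as did those of the conjugating enzyme, drug transporter, gastric gland and red blood cell lists (adjusted p from 0.0777 to 0.135). Without array 2 those of ABCB1, ABCG2, CYP4F2, NTHL1, SLC15A1, UGT2B7 and XDH ended (adjusted p from 0.0544 to 0.175), and that of the metallothioneins (adjusted p = 0.0567). The drug transporter list also lost its call without duodenum 1, 3, 8 or 10 (adjusted p = 0.0603, 0.0502, 0.0519 and 0.0501). The red blood cell list lost its call without duodenum 4 or 5 (adjusted p = 0.0548 and 0.051) or without ileum 3 and colon 3 (adjusted p = 0.0761). Against same-set duodenum arrays ABCB1, ABCG2 and UGT2B7 no longer passed (adjusted p from 0.0503 to 0.117), and with the block ABCB1 did not (adjusted p = 0.0691).

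Caco-2 cells 4 days after seeding were set against the same duodenum arrays. Cell cycle genes were higher in nearly the whole list. Most measured brush border hydrolases and conjugating enzymes were lower, but neither list passed with an estimated correlation (adjusted p = 0.15 for each). DKK1, a secreted inhibitor of Wnt signalling, was higher by 7.85 ± 0.21 or more, SLC2A3 by 6.49 ± 0.61 and GPC3 by 6.48 ± 0.67, and FGG was at least 86.0-fold higher, with adjusted p of at most 3.11e-07. DEFA5 differed by -9.75 ± 0.77 or lower, APOA4 by -9.62 ± 1.14 or lower, IGLC1 by -9.55 ± 0.83 or lower and REG1A by -9.01 ± 0.95 or lower, with adjusted p of at most 2.09e-06. Of the 49 cell cycle genes 45 were higher (47 adjusted over the list alone; adjusted p = 5.53e-19, adjusted p = 0.0359 with an estimated correlation). UBE2C was at 4.88 ± 0.69. Of the 23 nucleoside kinases and related enzymes 8 were higher and 6 lower (9 and 6 adjusted over the list alone; adjusted p = 0.994). ADA was at -5.31 ± 0.40, the surface nucleotidase NT5E at -3.83 ± 0.34 or lower and AHCY at 3.43 ± 0.27. Of the 4 nucleoside transporters 1 was higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.497). SLC28A2 was at -5.39 ± 0.76, SLC28A1 at -3.49 ± 0.68 or lower and SLC29A1 at 1.64 ± 0.39. P450 enzymes were lower in 7 of 22 in both adjustments (adjusted p = 0.012, adjusted p = 0.0732 with an estimated correlation). CYP3A4 was at -8.30 ± 1.17 or lower. Conjugating enzymes were lower in 12 and higher in 2 of 21 in both adjustments (adjusted p = 0.000164, adjusted p = 0.15 with an estimated correlation). CES2 was at -5.68. The 19 drug transporters, 2 higher and 7 lower, did not shift (adjusted p = 0.122), nor did the 19 amino acid and sugar transporters, 6 higher and 4 lower (7 and 4 adjusted over the list alone; adjusted p = 0.132). SLC5A1 was at -7.86 or lower and the amino acid transporter SLC7A5 at 3.91 ± 0.35. Brush border hydrolases were lower in 13 of 15 (adjusted p = 3.34e-09, adjusted p = 0.15 with an estimated correlation), with ANPEP at -7.42, and metallothioneins, which bind zinc and copper, in 8 of 8 (adjusted p = 9.5e-05, adjusted p = 0.169 with an estimated correlation), in both adjustments. Hepatocyte secreted proteins were higher in 16 and lower in 1 of 24 (17 and 1 adjusted over the list alone; adjusted p = 1.23e-12, adjusted p = 0.000909 with an estimated correlation). Interferon response genes were lower in 20 and higher in 1 of 29 (adjusted p = 8.62e-10, adjusted p = 0.0359 with an estimated correlation) in both adjustments. Enteroendocrine genes were lower in 8 of 13 in both adjustments (adjusted p = 4.92e-06, adjusted p = 0.038 with an estimated correlation). Cholesterol synthesis genes were higher in 11 and lower in 1 of 15, immediate early genes lower in 11 and higher in 1 of 35, fibroblast and matrix genes lower in 14 and higher in 4 of 28 (16 and 4 adjusted over the list alone), and lipid absorption genes lower in 5 and higher in 2 of 14 (7 and 2 adjusted over the list alone). Members were lower in 11 of 23 T and NK cell genes, 9 of 21 colon epithelium genes, 9 of 17 smooth muscle genes, 7 of 10 MHC class II genes, 7 of 19 myeloid genes, 6 of 8 Paneth cell genes, 6 of 15 iron and proximal gut genes, 6 of 17 B and plasma cell genes, 5 of 9 goblet cell genes, 4 of 12 endothelial genes and 3 of 10 gastric gland genes (11, 9, 12, 7, 7, 7, 6, 7, 6, 4 and 3 adjusted over the list alone). These last 15 lists had adjusted p of at most 0.0169, and adjusted p from 0.0633 to 0.396 with an estimated correlation. In all, 2213 genes differed, 1169 higher and 1044 lower, and 23 lists passed, 4 of them with an estimated correlation. The count was 1946 with the scaling set as a block, 1673 against same-set duodenum arrays, and 1420 without array 2 of day 4. The share of higher calls was 52.8%, and 78.5% on deposited values, whose median lay 0.67 higher in the cells. The 3' to 5' ratios of GAPDH and ACTB, measures of RNA quality, differed by -0.73 and -0.48. Without array 1 of day 4 the P450, endothelium, gastric gland, goblet cell, lipid absorption and myeloid lists no longer passed (adjusted p from 0.0586 to 0.135).

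The next comparison followed the Caco-2 layer from day 4 to day 16. Liver-type secreted proteins rose as a set. Cell cycle genes were lower as a set, but not with an estimated correlation (adjusted p = 0.0874). Few drug and nucleoside handling genes passed, as few of all did, and recovery was low, so the rest may have changed too. SERPINC1 (antithrombin) was at least 17.9-fold higher on day 16 (adjusted p = 4e-10). CPS1, the first enzyme of the urea cycle, rose by 3.92 ± 0.79 or more, the plasma protein ITIH2 by 3.60 ± 0.30, the kinin precursor KNG1 by 3.37 ± 0.76, the transcription factor MAF by 3.27 ± 0.67 and the lipolysis inhibitor G0S2 by 3.24 ± 0.80, with adjusted p from 2.5e-07 to 0.0477. DKK1 fell by 4.86 ± 0.28, ID1, an inhibitor of differentiation, fell by 3.69 ± 0.74, and UCHL1, a ubiquitin hydrolase, fell by 3.67 ± 0.57 or more. The chitinase-like CHI3L1 fell by 3.57 ± 0.55 or more, the neuropeptide gene GAL fell by 3.14 ± 0.49 and the lipoprotein receptor OLR1 fell by 3.05 ± 0.37, and these 6 falls had adjusted p from 4e-10 to 0.014. Of the 24 hepatocyte secreted proteins 6 rose (10 adjusted over the list alone; adjusted p = 1.1e-12, adjusted p = 0.000889 with an estimated correlation). AFP was at 2.67 ± 0.36 and ALB at 2.44 ± 0.48. Of the 49 cell cycle genes 3 fell (10 adjusted over the list alone; adjusted p = 1.4e-16, adjusted p = 0.0874 with an estimated correlation). KIF23, a motor of cell division, was at -1.80 ± 0.41. The conjugating enzymes and esterases rose as a set (adjusted p = 0.00783, adjusted p = 0.614 with an estimated correlation), with no single member past the test and 1 when adjusted over the list alone. Their largest difference was 2.75 ± 0.78 for the epoxide hydrolase EPHX2 (adjusted p = 0.0911). Of the 23 nucleoside kinases and related enzymes 2 rose and 1 fell (2 and 2 adjusted over the list alone; adjusted p = 0.285). NT5E was at 1.85 ± 0.44 or more and DUT, which hydrolyses dUTP, at -1.78 ± 0.34. None of the 4 nucleoside transporters, 22 P450 enzymes, 19 drug transporters or 19 amino acid and sugar transporters passed over all genes, and 1 of the last group was lower when adjusted over the list alone. The set tests gave adjusted p = 0.848 for each of the first 3 lists and 0.166 for the last. Brush border hydrolases had a median difference of 0.05 and a mean of 0.95, and none passed (adjusted p = 0.289). The 3' to 5' ratios of GAPDH and ACTB were above those of day 4 on both day 16 arrays, by 0.40 and 0.54 (exact p = 0.333, the smallest that 6 splits allow). In all, 105 genes changed, 64 up and 41 down, with 906 at an unadjusted p under 0.05. On deposited values 20 passed, 35% of them higher against 61% here. With only these 4 arrays in the model 0 genes passed, with 747 at an unadjusted p under 0.05, so the calls rest on the spread shared with the other groups. With 1 array left out the count was 207 and 62 without arrays 1 and 2 of day 4, and 69 and 30 without arrays 1 and 2 of day 16, where the lone array was taken to vary like the other groups. Without ileum 3 and colon 3 it was 344. The call of G0S2 ended without any single one of the 4 arrays, those of ID1, KNG1, DUT and ALB without array 1 of day 4 (ALB at 1.40) or array 2 of day 16, and that of KIF23 without these or array 2 of day 4. Those of NT5E and CPS1 ended without array 2 of day 4, array 1 of day 16 or, in turn, array 1 of day 4 and array 2 of day 16, and that of MAF without array 2 of day 4 or array 1 of day 16, and all these losses had adjusted p from 0.0539 to 0.425. The conjugating enzymes no longer passed as a set without array 1 of day 4 (adjusted p = 0.0524). On deposited values CPS1, DUT, G0S2, GAL, KNG1, MAF and NT5E did not pass (adjusted p of at least 0.052), nor did G0S2 with the scaling set as a block (adjusted p = 0.0586), where 92 genes passed.

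Day 16 Caco-2 cells were also set against colon tissue. Most measured hepatocyte secreted proteins were higher in the cells, and most measured genes of smooth muscle, of fibroblasts and matrix and of myeloid cells were lower. These 4 lists also passed with an estimated correlation (adjusted p from 2.24e-05 to 0.0323). APOA1 was at least 1002-fold higher, AFP at least 534-fold and APOB at least 392-fold, and APOC3 was higher by 8.13 ± 1.64, with adjusted p of at most 0.000907. The smooth muscle actins ACTG2 and ACTA2 were at least 877-fold and 778-fold lower, the haemoglobin gene HBB differed by -9.06 ± 0.64 or lower and the muscle myosin MYH11 by -8.83 ± 0.43, with adjusted p of at most 1.81e-09. Of 24 hepatocyte secreted proteins 20 were higher (21 adjusted over the list alone; adjusted p = 5.36e-23, adjusted p = 2.24e-05 with an estimated correlation). Of 15 cholesterol synthesis genes 12 were higher in both adjustments (adjusted p = 7.21e-10, adjusted p = 0.0172 with an estimated correlation), with HMGCS1 higher by 5.05 ± 0.44 or more. Of 19 amino acid and sugar transporters 6 were higher in both adjustments (adjusted p = 0.0028, adjusted p = 0.0223 with an estimated correlation). SLC7A7 was at 7.18 ± 0.82. Of 17 smooth muscle genes 16 were lower (17 adjusted over the list alone; adjusted p = 6.51e-26, adjusted p = 0.0172 with an estimated correlation). Of 28 fibroblast and matrix genes 22 were lower (24 adjusted over the list alone; adjusted p = 1.84e-19, adjusted p = 0.0323 with an estimated correlation). The filament gene VIM was at -8.09 ± 0.79. Conjugating enzymes were higher in 6 and lower in 1 of 21 (9 and 1 adjusted over the list alone; adjusted p = 0.0109, adjusted p = 0.312 with an estimated correlation). The nucleoside kinases and related enzymes, 4 higher and 3 lower of 23, did not shift (adjusted p = 0.954). AHCY was at 3.04 ± 0.32 and DPYD at least 9.75-fold lower. The 4 nucleoside transporters held 1 higher member, SLC29A2 at 1.94 ± 0.59 (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.919). The 22 P450 enzymes held 2 higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.999) and the 19 drug transporters 4 higher in both adjustments (adjusted p = 0.189). ABCC2 was at least 22.6-fold higher and SLCO2B1 at 4.40 ± 0.72. Myeloid genes were lower in 10 of 19 (adjusted p = 1.8e-06, adjusted p = 0.0227 with an estimated correlation) and immediate early genes lower in 16 and higher in 1 of 35 (adjusted p = 1.97e-05, adjusted p = 0.039 with an estimated correlation), in both adjustments. Members were higher in 21 of 49 cell cycle genes, 6 of 14 lipid absorption genes and 6 of 15 iron and proximal gut genes (30, 6 and 6 adjusted over the list alone). Members were lower in 14 of 29 interferon response genes, 11 of 18 neuron and glia genes, 8 of 12 endothelial genes, 7 of 10 MHC class II genes and 5 of 17 B and plasma cell genes (15, 14, 8, 7 and 5 adjusted over the list alone). These 8 lists had adjusted p of at most 0.022, and adjusted p from 0.0802 to 0.5 with an estimated correlation. Red blood cell genes, 1 of 4 lower, and T and NK cell genes, 4 of 23 lower (1 and 3 adjusted over the list alone), did not shift (adjusted p = 0.189 and 0.175). In all, 1819 genes differed, 856 higher and 963 lower, and 16 lists passed, 7 of them with an estimated correlation. No scaling set holds both groups, and with the set as a block, estimated through duodenum, 1143 genes differed (477 higher, 666 lower). The share of higher calls was 47.1% and, on deposited values, 86.2% of 2751 calls, with a median shift of 1.08. The count was 819 with only these 5 arrays in the model, 1171 without array 1 of day 16 and 983 without array 2. SLC29A2 lost its call without either of these arrays or without colon 2 (adjusted p = 0.085, 0.111 and 0.111, with a difference of 1.12 without colon 2), the iron and proximal gut list without array 2 (adjusted p = 0.0707) and on deposited values (adjusted p = 0.0815), and the B and plasma cell list without colon 3 (adjusted p = 0.165).

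Among the tissue means, the rank order of genes in Caco-2 cells was closest to duodenum, a likeness that may not be regional. Over the 7167 genes the mean Spearman correlation of the day 16 arrays with the tissue mean was 0.758 for duodenum, 0.669 for ileum, 0.666 for colon and 0.582 for jejunum. On day 4 it was 0.699, 0.637, 0.640 and 0.579. These means pool unlike arrays in different numbers. Jejunum, ileum 1 and 2 and colon 1 and 2, high in muscle and low in brush border genes, reached at most 0.611 singly. Array 1 of day 16 correlated with ileum 3 and colon 3 at 0.722 and 0.719, inside its range over duodenum arrays (0.702 to 0.768). Array 2 was at 0.675 and 0.669, below its range (0.693 to 0.731). On day 4 array 1 was at 0.665 and 0.697, inside 0.645 to 0.710, and array 2 at 0.593 and 0.625, below 0.641 to 0.678. These correlations run across genes, which are not independent replicates.

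Jejunum was set against duodenum, but cell type genes differed too, so this cannot place enzymes along the gut. Most measured genes of smooth muscle, enteric neurons and glia, fibroblasts and myeloid cells were higher in jejunum, and most measured genes of the brush border and of lipid absorption were lower. None of these 6 lists passed with an estimated correlation (adjusted p from 0.0636 to 0.176). The fatty acid carrier FABP4 was higher by 6.68 ± 0.73, the methyltransferase NNMT by 6.58 ± 0.81, the matrix protein SPP1 by 6.17 ± 0.79 and the neutrophil protein S100A8 by 6.06 ± 0.65, with adjusted p of at most 1.34e-05. APOB was at least 521-fold lower, LCT at least 285-fold and SLC5A1 at least 258-fold, and the peptidase MEP1A differed by -7.65 ± 1.38 or lower, with adjusted p of at most 0.000295. Brush border hydrolases were lower in 14 of 15 (adjusted p = 1.28e-09, adjusted p = 0.159 with an estimated correlation), lipid absorption genes in 11 of 14 with 1 higher (adjusted p = 8.25e-05, adjusted p = 0.176 with an estimated correlation), and conjugating enzymes in 13 of 21 (adjusted p = 2.44e-05, adjusted p = 0.129 with an estimated correlation). UGT2B7 was at -6.48 ± 0.95 or lower. These counts were the same adjusted over the list alone. Smooth muscle genes were higher in 16 of 17 (adjusted p = 1.93e-12, adjusted p = 0.129 with an estimated correlation), with the muscle filament DES at 4.49 ± 0.48. Enteric neuron and glia genes were higher in 14 of 18 (adjusted p = 1.28e-09, adjusted p = 0.124 with an estimated correlation). UCHL1 was at least 64.5-fold higher. Both counts were the same adjusted over the list alone. Fibroblast and matrix genes were higher in 26 of 28 (27 adjusted over the list alone; adjusted p = 5.07e-14, adjusted p = 0.124 with an estimated correlation). Among the 23 nucleoside kinases and related enzymes 4 were higher and 6 lower (5 and 6 adjusted over the list alone; adjusted p = 0.799). ADA was at -5.76 ± 0.40 and AOX1, an aldehyde oxidase that also oxidises purines, at 3.87 ± 0.70. Of the 4 nucleoside transporters 1 was higher and 2 lower in both adjustments (adjusted p = 0.248). SLC28A2 was at -5.49 ± 0.76, SLC28A1 at -3.45 ± 0.68 or lower and SLC29A1 at 1.52 ± 0.39. Of the 22 P450 enzymes 2 were higher and 7 lower (3 and 7 adjusted over the list alone; adjusted p = 0.113). CYP3A4 was at -7.00 ± 1.17 and CYP1B1, a P450 of many cell types outside the liver, at 4.14 ± 0.43 or more. Of the 19 drug transporters 1 was higher and 9 lower (3 and 10 adjusted over the list alone; adjusted p = 0.00605, adjusted p = 0.176 with an estimated correlation). ABCC3 was at -5.37 ± 0.74 or lower. The 19 amino acid and sugar transporters, 2 higher and 7 lower (3 and 8 adjusted over the list alone), did not shift (adjusted p = 0.0832). Myeloid genes were higher in 12 of 19 and endothelial genes in 10 of 12. Members were lower in 10 of 21 colon epithelium genes, 9 of 15 iron and proximal gut genes, 6 of 9 goblet cell genes and 6 of 10 gastric gland genes. All 6 counts were the same adjusted over the list alone, where 1 myeloid gene was also lower. Cell cycle genes were lower in 15 and higher in 1 of 49 (14 and 1 adjusted over the list alone). These 7 lists had adjusted p of at most 0.0118, and adjusted p from 0.0636 to 0.479 with an estimated correlation. The 3' to 5' ratios of GAPDH and ACTB differed by 0.79 and 0.61. In all, 2599 genes differed, 1342 higher and 1257 lower, and 14 lists passed, none of them with an estimated correlation. The count was 2248 with the scaling set as a block and 2017 against the 5 duodenum arrays of the same set, and the share of higher calls was 51.6%, against 26.7% on deposited values, whose median lay at -0.44. It was 1550 without jejunum 1 and 1334 without jejunum 2. SLC29A1 lost its call without jejunum 2 (adjusted p = 0.0658) and on deposited values (adjusted p = 0.179).

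Ileum was compared with duodenum over 3 arrays, of which ileum 3 stood apart. Most measured genes of smooth muscle and of fibroblasts and matrix were higher in ileum, and most measured brush border, lipid absorption and conjugating enzyme genes were lower. None of these 5 lists passed with an estimated correlation (adjusted p from 0.0836 to 0.155). FABP4 was higher by 5.52 ± 0.62, NNMT by 5.40 ± 0.69, SPP1 by 4.99 ± 0.67, the muscle filament genes SYNM and DES by 4.74 ± 0.38 and 4.69 ± 0.41, and S100A8 by 4.69 ± 0.55, with adjusted p of at most 2.44e-05. The calcium-binding protein S100G, which carries calcium across duodenal cells, was at least 108-fold lower (adjusted p = 8.17e-10). LCT differed by -6.91 ± 0.94, ADA by -6.39 ± 0.34, the protease gene CTSE by -5.75 ± 0.49, the steroid dehydrogenase HSD17B2 by -5.29 ± 0.90 and the intestinal phosphatase ALPI by -4.95 ± 0.77, with adjusted p of at most 0.000234. The 23 nucleoside kinases and related enzymes held 5 higher and 4 lower members (5 and 5 adjusted over the list alone; adjusted p = 0.461). Besides ADA these included AMPD1, which deaminates AMP, at -2.08 ± 0.26 or lower and AOX1 at 2.35 ± 0.59. Of the 4 nucleoside transporters 1 was higher and 2 lower in both adjustments (adjusted p = 0.282). SLC28A2 was at -4.86 ± 0.65, SLC28A1 at -2.08 ± 0.58 (-3.45 without ileum 3 and -1.32 without ileum 1) and SLC29A1 at 1.74 ± 0.33. P450 enzymes were lower in 7 and higher in 1 of 22 in both adjustments (adjusted p = 0.0322, adjusted p = 0.112 with an estimated correlation). CYP3A4 was at -5.62 ± 1.00, CYP2J2 at -3.95 ± 0.90 (-6.17 without ileum 3) and CYP1A1 at -3.43 ± 0.54. Conjugating enzymes were lower in 15 of 21 (16 adjusted over the list alone; adjusted p = 4.4e-07, adjusted p = 0.0836 with an estimated correlation). UGT2B7 was at -4.14 and the quinone reductase NQO1 at -3.32 ± 0.54. Drug transporters were lower in 6 of 19 (7 adjusted over the list alone; adjusted p = 0.00394, adjusted p = 0.139 with an estimated correlation), and amino acid and sugar transporters were lower in 6 and higher in 2 of 19 in both adjustments (adjusted p = 0.0213, adjusted p = 0.0836 with an estimated correlation). SLC5A1 was at -5.54 ± 0.92.

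Brush border hydrolases were lower in ileum in 12 of 15 (13 adjusted over the list alone; adjusted p = 5.8e-08, adjusted p = 0.155 with an estimated correlation). TMPRSS15, the enteropeptidase that activates trypsinogen, was at -4.71 ± 0.41. The iron, vitamin and proximal gut genes were lower in 7 of 15 (7 lower and 1 higher adjusted over the list alone; adjusted p = 3.92e-05, adjusted p = 0.0836 with an estimated correlation). The proximal gut transcription factor GATA4 was at -3.21 ± 0.21. Smooth muscle genes were higher in 16 of 17 in both adjustments (adjusted p = 6.4e-18, adjusted p = 0.0836 with an estimated correlation), and enteric neuron and glia genes in 10 of 18 (14 adjusted over the list alone; adjusted p = 5.8e-08, adjusted p = 0.112 with an estimated correlation). The neuropeptide gene VIP was at 3.61. B and plasma cell genes were lower in 4 and higher in 1 of 17 (9 and 1 adjusted over the list alone; adjusted p = 0.0105, adjusted p = 0.361 with an estimated correlation). The antibody-joining chain JCHAIN was at -2.50 ± 0.63. Cholesterol synthesis genes were lower in 8 of 15 in both adjustments (adjusted p = 0.000867, adjusted p = 0.121 with an estimated correlation). MHC class II genes were lower in 3 of 10 (6 adjusted over the list alone; adjusted p = 0.0222, adjusted p = 0.361 with an estimated correlation), and this set no longer passed with the scaling set as a block (adjusted p = 0.0969) or against same-set duodenum arrays (adjusted p = 0.115). Fibroblast and matrix genes were higher in 25 of 28, immediate early genes in 10 of 35, myeloid genes in 9 with 2 lower of 19, and endothelial genes in 6 of 12 (25, 10, 13 and 9 adjusted over the list alone). Members were lower in 10 of 14 lipid absorption genes with 1 higher, 10 of 49 cell cycle genes, 8 of 21 colon epithelium genes, 6 of 10 gastric gland genes, 5 of 13 enteroendocrine genes with 1 higher, 4 of 8 Paneth cell genes with 1 higher, 3 of 7 pancreatic genes and 2 of 9 goblet cell genes (11, 6, 9, 6, 6, 6, 3 and 4 adjusted over the list alone). These 12 lists had adjusted p of at most 0.0322, and adjusted p from 0.0836 to 0.436 with an estimated correlation. The brush border list had a mean level of 11.16 on ileum 3, inside the duodenum range of 10.61 to 11.33. CYP3A4 stood at the floor of 4.79 on ileum 1 and 2 and at 12.91 on ileum 3, while ADA was at 7.77, 8.11 and 6.91 on the 3 ileum arrays, against 13.24 to 14.51 in duodenum. In all, 1978 genes differed between ileum and duodenum, 1036 higher and 942 lower, and 23 lists passed, none of them with an estimated correlation. The count was 1591 with the scaling set as a block (844 higher, 747 lower) and 1267 against same-set duodenum arrays (717 higher, 550 lower). It was 850 without ileum 1, 991 without ileum 2, and 3058 when ileum 3 and colon 3 were both left out, of which 1900 were among the 1978. The share of higher calls was 52.4%, and 21.5% on deposited values, whose median lay at -0.46. AOX1, CYP2J2, JCHAIN and SLC28A1 no longer passed without ileum 1 or without ileum 2 (adjusted p from 0.0576 to 0.172), nor did the goblet, Paneth and pancreatic lists, joined without ileum 1 by the colon epithelium and MHC class II lists (adjusted p from 0.0524 to 0.157). The P450 list no longer passed without ileum 3 (adjusted p = 0.0621). On deposited values AOX1, the P450, MHC class II and pancreatic lists did not pass (adjusted p from 0.0652 to 0.268), and against same-set duodenum arrays SLC28A1 did not (adjusted p = 0.0611).

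Colon was set against duodenum as the far end of the gut. All 17 measured smooth muscle genes were higher, and most measured genes of lipid absorption, the brush border and Paneth cells were lower. None of these 4 lists passed with an estimated correlation (adjusted p from 0.0552 to 0.0736). The muscle proteins CNN1, SYNM and DES were higher by 5.88 ± 0.39, 5.74 ± 0.38 and 5.59 ± 0.41, the matrix protein THBS4 by 5.53 ± 0.57, the calmodulin-binding PCP4 by 5.38 ± 0.47 and ACTG2 by 5.28 ± 0.34, with adjusted p of at most 4.77e-07. The apolipoproteins APOA1 and APOB were at least 1271-fold and 521-fold lower, APOA4 differed by -9.52 ± 0.97 or lower, APOC3 by -9.04 ± 1.18, DEFA6 by -8.67 ± 0.98 or lower and DEFA5 by -8.52 ± 0.65, with adjusted p of at most 8.63e-06. The 23 nucleoside kinases and related enzymes held 3 higher and 5 lower members (4 and 5 adjusted over the list alone; adjusted p = 0.148). ADA was at -6.52 ± 0.34, XDH at -3.31 ± 0.58 and AMPD1 at -2.41 ± 0.26 or lower. Of the 4 nucleoside transporters 1 was higher and 2 lower in both adjustments (adjusted p = 0.141). SLC28A2 was at -5.36 ± 0.65, SLC28A1 at -3.57 ± 0.58 or lower and SLC29A1 at 2.11 ± 0.33. P450 enzymes were lower in 9 and higher in 1 of 22 in both adjustments (adjusted p = 0.00161, adjusted p = 0.0552 with an estimated correlation). CYP3A4 was at -6.93 ± 1.00 and CYP3A5 at -4.30 ± 0.51. Conjugating enzymes were lower in 16 of 21 (17 adjusted over the list alone; adjusted p = 3.11e-08, adjusted p = 0.0552 with an estimated correlation). UGT2B7 was at -6.25 ± 0.81. Drug transporters were lower in 10 and higher in 1 of 19 in both adjustments (adjusted p = 0.000164, adjusted p = 0.0608 with an estimated correlation). SLC15A1 was at -4.66 or lower, ABCC2 at least 23.9-fold lower and the folate carrier SLC19A1 at -2.78 ± 0.30. Amino acid and sugar transporters were lower in 8 and higher in 2 of 19 in both adjustments (adjusted p = 0.0147, adjusted p = 0.0552 with an estimated correlation). SLC5A1 was at -7.67 ± 0.92 and SLC7A7 at -5.24 ± 0.59. Brush border hydrolases were lower in 14 of 15 (adjusted p = 2.19e-13, adjusted p = 0.0617 with an estimated correlation), with ANPEP at -7.80 ± 0.98, and Paneth cell genes in 7 of 8 (adjusted p = 6.9e-07, adjusted p = 0.0736 with an estimated correlation). Smooth muscle genes were higher in 17 of 17 (adjusted p = 2.6e-20, adjusted p = 0.0552 with an estimated correlation) and enteric neuron and glia genes in 13 of 18 (adjusted p = 4.05e-07, adjusted p = 0.0875 with an estimated correlation). These 4 counts were the same adjusted over the list alone. B and plasma cell genes were lower in 4 and higher in 1 of 17 in both adjustments (adjusted p = 0.0383, adjusted p = 0.488 with an estimated correlation). IGHM was at -3.62 ± 0.76 (-5.57 without colon 3). Fibroblast and matrix genes were higher in 26 of 28, myeloid genes in 7 with 2 lower of 19, and endothelial genes in 5 of 12 (27, 8 and 6 adjusted over the list alone). Members were lower in 11 of 14 lipid absorption genes with 1 higher, 8 of 15 iron and proximal gut genes, 7 of 15 cholesterol synthesis genes, 6 of 13 enteroendocrine genes, 6 of 10 gastric gland genes, 5 of 23 T and NK cell genes, 5 of 10 MHC class II genes, 3 of 7 pancreatic genes and 2 of 5 ileal bile acid genes, the same adjusted over the list alone, and in 7 of 49 cell cycle genes with 1 higher (1 and 0 adjusted over the list alone). These 13 lists had adjusted p of at most 0.0389, and adjusted p from 0.0552 to 0.514 with an estimated correlation. In all, 2187 genes differed, 1220 higher and 967 lower, and 22 lists passed, none of them with an estimated correlation. The count was 1841 with the scaling set as a block (1040 higher, 801 lower) and 1565 against same-set duodenum arrays (904 higher, 661 lower), and the T and NK cell and endothelium lists passed in neither (adjusted p from 0.0706 to 0.0986). It was 1258 without colon 1 and 1279 without colon 2. The share of higher calls was 55.8%, and 27.8% on deposited values, whose median lay at -0.44. The B and plasma cell, cell cycle and endothelium lists lost their calls without colon 1 (adjusted p from 0.0882 to 0.305), and these and the T and NK cell list without colon 2 (adjusted p from 0.125 to 0.165). The ileal bile acid and myeloid lists lost theirs without colon 3 (adjusted p = 0.06 and 0.133), and the pancreatic and T and NK cell lists on deposited values (adjusted p from 0.0605 to 0.061).

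**Figure D2:**
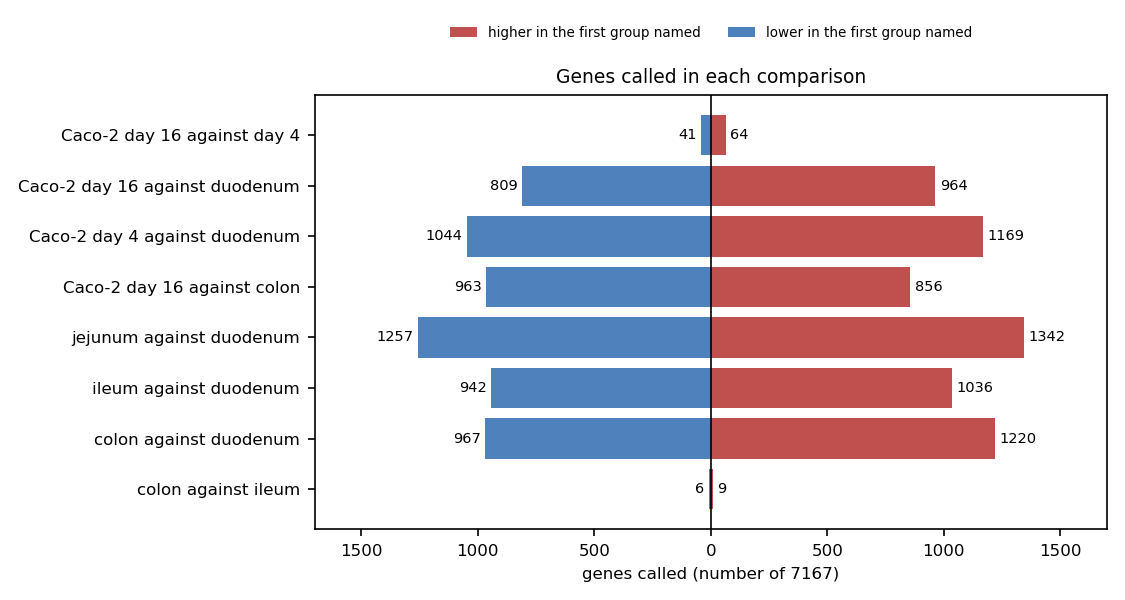
Number of genes with an adjusted p under 0.05 that were higher (bars to the right of 0) or lower (bars to the left) in the first group named (horizontal axis), in each of the 8 comparisons, out of 7167 genes. The counts run from 15 for colon against ileum to 2599 for jejunum against duodenum.

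Colon and ileum were compared directly, within a single scaling set. Few genes passed, and the Paneth cell defensin DEFA5 had the largest difference among them. DEFA5 differed by -6.90 ± 0.81 (adjusted p = 0.000286), the homeobox gene HOXC6 by -3.09 ± 0.51, the adipose-linked ADIRF by -2.28 ± 0.38 and SST by -2.27 ± 0.40, with adjusted p of at most 0.0121. The cardiac actin gene ACTC1 was higher in colon by 3.29 ± 0.68, the phosphodiesterase PDE3B by 2.65 ± 0.42 or more, the dehydrogenase HSD17B6 by 2.46 ± 0.41 or more and the neurotensin receptor NTSR1 by 2.14 ± 0.42, with adjusted p of at most 0.0419. Paneth cell genes were lower in 1 of 8 (5 adjusted over the list alone; adjusted p = 2.66e-10, adjusted p = 0.134 with an estimated correlation), and DEFA6 differed by -5.35 ± 1.21 or lower without passing (adjusted p = 0.0742). Metallothioneins were lower as a set, with 0 of 8 past the test over all genes and 5 adjusted over the list alone (adjusted p = 9.37e-08, adjusted p = 0.147 with an estimated correlation). Ileal bile acid genes were lower as a set, with 0 of 5 and 2 adjusted over the list alone (adjusted p = 0.00128, adjusted p = 0.147 with an estimated correlation), and their carrier FABP6 had a difference of -4.75 ± 1.13 (adjusted p = 0.0905). Smooth muscle genes were higher as a set, with 0 of 17 and 4 adjusted over the list alone (adjusted p = 1.79e-07, adjusted p = 0.233 with an estimated correlation). The brush border, lipid absorption, enteroendocrine, hepatocyte, myeloid, T and NK cell, endothelium and immediate early lists were lower as sets and the fibroblast and hypoxia lists higher, with adjusted p from 1.49e-08 to 0.0484, and adjusted p from 0.147 to 0.446 with an estimated correlation. Among these only SST, of the enteroendocrine list, and the fibroblast gene FN1, higher by 1.61 ± 0.28 (adjusted p = 0.0107), passed by themselves over all genes. Adjusted over the list alone, 4 fibroblast genes, 2 myeloid genes, 1 lipid absorption gene and 1 enteroendocrine gene passed. The glycosylases (adjusted p = 0.302), the kinases and related enzymes (adjusted p = 0.213), the nucleoside transporters (adjusted p = 0.302) and the amino acid and sugar transporters (adjusted p = 0.129) did not shift, and none of their members passed over all genes. P450 enzymes were lower as a set with none of 22 members past the test (adjusted p = 0.00982, adjusted p = 0.134 with an estimated correlation), as were drug transporters with none of 19, or 2 adjusted over the list alone (adjusted p = 0.0252, adjusted p = 0.27 with an estimated correlation). In all, 15 genes passed, 9 higher and 6 lower, with 610 at an unadjusted p under 0.05, and 16 lists passed, none of them with an estimated correlation. With the array number as a block 93 genes passed (56 higher, 37 lower), among them all 15. On deposited values 1 gene passed, and it was lower in colon, so the share of higher calls was 0% against 60% here. The count was 30 without ileum 1, 148 without ileum 3, 3 without colon 1, 7 without colon 2 and 114 without colon 3. With ileum 3 and colon 3 both left out it was 173, all 15 among them, and 8 of the 16 lists still passed. With only these 6 arrays in the model 0 genes passed, with 278 at an unadjusted p under 0.05. The calls of ACTC1, FN1, HOXC6, HSD17B6, NTSR1, PDE3B and SST ended without colon 1 (adjusted p from 0.0657 to 0.289), those of ACTC1, FN1, NTSR1 and SST without colon 2 (adjusted p from 0.0678 to 0.294), ACTC1 also without ileum 1 (adjusted p = 0.0645) and ACTC1 and NTSR1 without ileum 2 (adjusted p = 0.0732 and 0.127). Without ileum 3, 10 of the lists no longer passed, among them brush border, smooth muscle, ileal bile acid, P450 and drug transporter genes (adjusted p from 0.0569 to 0.886), against 5 without colon 1, 4 without colon 2, 2 without colon 3, 1 without ileum 1 and 4 without ileum 2.

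**Figure D3:**
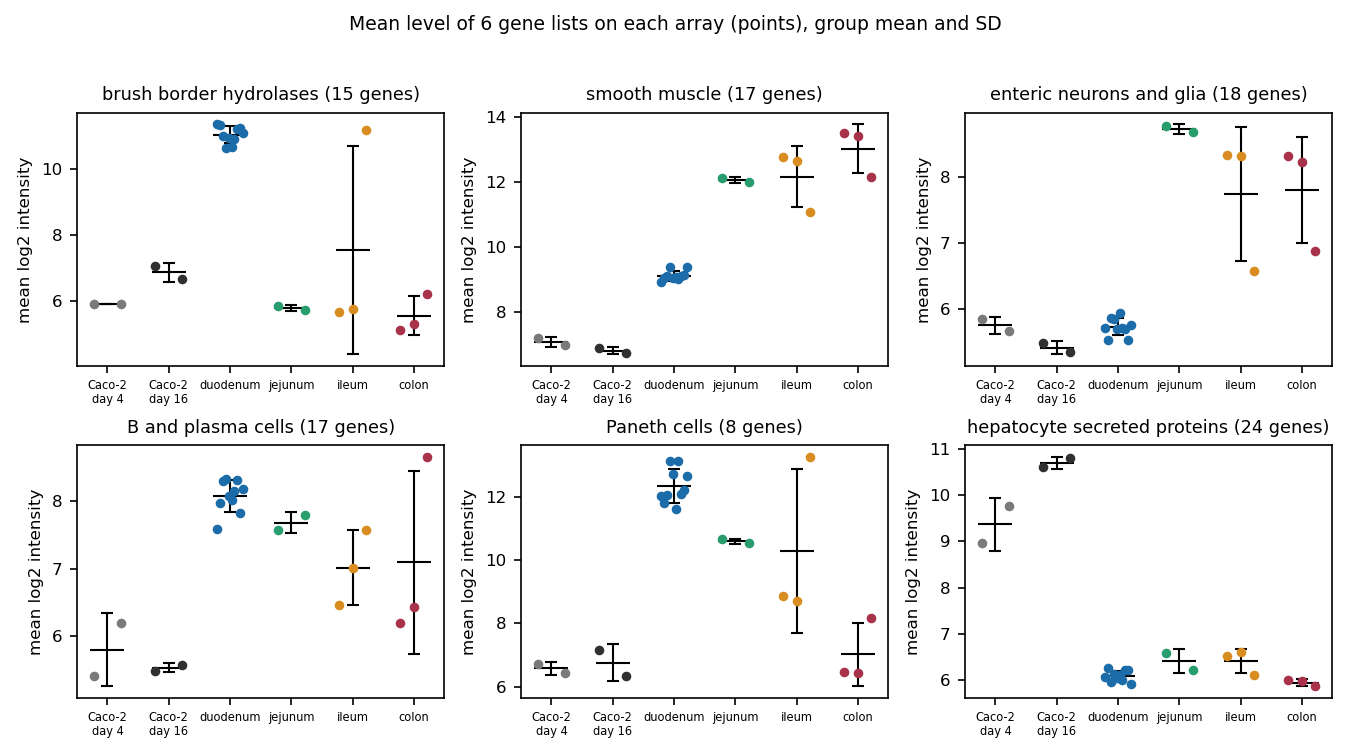
Mean log2 normalised intensity (vertical axis) of 6 gene lists on each array, by group (horizontal axis), with 1 point per array, the group mean and its SD. The brush border mean is 11.02 on the duodenum arrays, 5.81 in jejunum and 5.57 in colon, and the smooth muscle mean is 9.11, 12.06 and 13.03.

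Cell type genes differed between the tissue groups, and RNA state was compared too. The mean level of the smooth muscle list was 9.11 ± 0.15 (SD, n = 10) in duodenum, 12.06 ± 0.10 (n = 2) in jejunum, 12.17 ± 0.94 (n = 3) in ileum and 13.03 ± 0.75 (n = 3) in colon, and that of the enteric neuron and glia list was 5.74 ± 0.13, 8.72 ± 0.07, 7.74 ± 1.01 and 7.81 ± 0.80. The brush border list had means of 11.02 ± 0.26, 5.81 ± 0.08, 7.54 ± 3.13 and 5.57 ± 0.59 in the same order. Ileum 3 correlated with the other ileum arrays at 0.678 and with the duodenum arrays at 0.865, and colon 3 at 0.782 and 0.813, across genes. The log2 ratio of the 3' to the 5' probe set of GAPDH, which rises as RNA is degraded, had means of 0.66 ± 0.33 in duodenum, 1.46 ± 0.11 in jejunum, 1.28 ± 0.45 in ileum, 0.92 ± 0.43 in colon, and -0.06 ± 0.12 and 0.34 ± 0.28 in Caco-2 cells on day 4 and day 16. The same ratio of ACTB had means of 0.72 ± 0.21, 1.33 ± 0.03, 1.12 ± 0.49 and 0.76 ± 0.36 in these tissues, and 0.25 ± 0.10 and 0.78 ± 0.18 in the cells. Differences from duodenum, of colon from ileum and of day 16 from day 4 were tested in 14 two-sided exact permutation tests, of which those of jejunum and Caco-2 cells were added after the values were seen. Jejunum differed by 0.79 for GAPDH and 0.61 for ACTB, and Caco-2 day 4 by -0.73 and -0.48 (exact p = 0.0152 for each, the smallest that 66 splits allow). Their Benjamini-Hochberg adjusted p was 0.0532 over the 14 tests, which did not pass, and 0.0456 over the 12 other than day 16 against day 4. Ileum differed by 0.62 (exact p = 0.0245 over 286 splits, adjusted 0.0686) and 0.40 (exact p = 0.0524, adjusted 0.122), and the other 8 tests had larger adjusted p, up to 0.825. Between the 2 scaling sets of duodenum arrays, 7 genes differed, 6 higher and 1 lower in the second set, with 290 at an unadjusted p under 0.05. For 10 genes named here, among them CYP2J2, UGT2B7, SLC15A1 and DEFA6, the gap from 1 of the 10 duodenum arrays to the nearest was large beside their range, and AOX1 was at the floor on 6 of them.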

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

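All tests of explanations in this part were chosen after the result was seen, except the one for RNA degradation.

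Smooth muscle genes were high on the jejunum, ileum and colon arrays, and brush border genes low on all but ileum 3 (mean 11.16). The mean smooth muscle level minus the mean brush border level exceeded that of duodenum by 8.00 ± 0.84 (SE, 8 against 10 arrays), and by 8.88 ± 0.32 without ileum 3. The scaling set is excluded as the cause, since this measure differed by 0.0704 (SE 0.23) between the duodenum arrays of the 2 sets, and RNA degradation as the whole cause, since the excess was 7.04 (SE 1.01) with the GAPDH 3' to 5' ratio as a covariate and 7.33 (SE 0.91) with that of ACTB. Less mucosa as the whole cause of the low brush border genes is argued against in jejunum, on ileum 1 and 2 and on colon 3, where 3 abundant B and plasma cell genes, which belong to the mucosa, lay 5.91, 3.42 and 5.68 above 10 abundant brush border genes in their shift from duodenum (their duodenum ranges sum to 1.67), while on colon 1 and 2 (2.10) it cannot be told apart from a low output of these hydrolases by colon itself. More muscle wall may account for the smooth muscle part, with neuron and glia genes of the wall at 2.27 (SE 0.26), while less mucosa as a part cause and a difference between the gut segments stay open, the last untested.

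Ileum 3 and colon 3 stood apart from arrays 1 and 2 of their groups. A duodenum sample under another label is excluded for both. On ileum 3 the ileal bile acid list mean lay 1.35 above the highest duodenum array (range 6.89 to 7.62). On colon 3 the colon epithelium list mean lay 1.70 above it (8.53 to 9.06). An exchange is excluded too, as ileal bile acid genes were 3.76 higher on ileum 3 than on colon 3. More mucosa (all cells gained alike) as the whole cause of the epithelial part is argued against on ileum 3. There abundant goblet genes exceeded abundant B and plasma cell genes by 4.25 in their difference from arrays 1 and 2 (summed duodenum ranges 2.38). On colon 3 (0.933) more mucosa may account for that part, and less muscle wall on both arrays for another, with neuron and glia genes at -1.56 on average and smooth muscle genes at -1.63 and -1.30 from arrays 1 and 2. More mucosa on ileum 3 stays open, as do differences between donors or in handling, which were not tested.

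Other groupings of the same arrays were counted. Of 100 splits only the real one called as many genes in ileum (1978, highest other 1336) and colon (2187, highest other 980) against duodenum. This argues against chance for both counts, if the arrays are independent. In colon against ileum 5 of the 10 splits called as many as the real 15, and the highest other, with ileum 1 and 2 and colon 2 on one side, called 673. The 10 splits are too few for a share under 0.05, and that count, many times the real one, points to a structure of the samples other than the labels. Of the splits that part all 3 same-number pairs, the real one called 15 genes (93 with the number as a block), and the other 3 called 0, 3 and 0 (0, 14 and 0 blocked).

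On the 10 duodenum arrays, the gap between the highest or lowest array and its nearest neighbour, as a share of the range, was large for 18 of 144 gene and list levels tested. Of these, 13 were among the 114 with no array at the floor, where chance gives about 1 in 20, and 5 were genes with 6 to 9 arrays at the floor (AOX1, CHI3L1, DKK1, NTSR1 and OLR1), where ties raise this share and no such rate holds. Duodenum 6 was lowest in CNN1 (0.519), DEFA6 (0.52) and DUT (0.614) and highest in NQO1 (0.479), the red blood cell list (0.482) and NTSR1 (1). Duodenum 2 was highest in ALPI (0.518), CYP2J2 (0.472), UGT2B7 (0.477) and DKK1 (0.752). Duodenum 7 was lowest in SLC15A1 (0.486) and highest in CHI3L1 (1) and OLR1 (0.625). Duodenum 4 was highest in AOX1 (0.646) and in the interferon response list (0.642), duodenum 3 was highest in CPS1 (0.493), duodenum 8 lowest in HMGCS1 (0.476) and duodenum 5 lowest in the amino acid and sugar transporter list (0.482).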

How the results depend on the processing

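The 4 alternatives added last were chosen only after the results were seen. Of the alternatives other than single arrays left out, the count of called genes stayed within 1.5 times of the reported one in 9 of 14 for Caco-2 day 16 against day 4, in 14 of 15 for day 16 against duodenum, 14 of 15 for day 4 against duodenum, 10 of 14 for day 16 against colon, 14 of 15 for jejunum, 11 of 15 for ileum and 13 of 15 for colon against duodenum, and 7 of 14 for colon against ileum. Day 16 against day 4 (105) gave 20 on the values as deposited, 257 with the floor at the 40th percentile, 0 with only the arrays of the 2 groups, 65 with array weights and 344 without ileum 3 and colon 3. Day 16 against colon (1819) gave 2751 as deposited, 819 with only the arrays of the 2 groups, 2787 with array weights and 1143 with the scaling set as a block. Ileum against duodenum (1978) gave 3335 with array weights, 1267 with duodenum arrays of the same set and 3058 without ileum 3 and colon 3, and colon against duodenum (2187) gave 3685 with array weights. Colon against ileum (15) gave 1 as deposited, 4 and 62 with the floor at the 10th and 40th percentile, 0 with only the arrays of the 2 groups, 323 with array weights, 93 with the replicate block and 173 without ileum 3 and colon 3. The arrays of the other comparisons share only a number, with correlations of same-number deviations from -0.187 to 0.222 (0.222 for both pairs of day 16 and day 4, a single value by construction with 2 arrays a group), and the replicate block, which spends degrees of freedom on numbers, gave 549 for day 16 and 913 for day 4 against duodenum, 599 for jejunum, 760 for ileum and 911 for colon against duodenum, 121 for day 16 against day 4 and 2039 against colon. With 1 array left out in turn the counts ranged from 30 to 207, 862 to 1757, 1420 to 2261, 983 to 2070, 1334 to 2658, 850 to 2846, 1258 to 2554 and 3 to 148, in the order of the first sentence on counts. The likeness of day 16 to duodenum (0.758) was 0.808 with no filter and 0.684 with a filter at the 60th percentile, whose construction adds or removes dim genes. Candidates that differed over the 6 groups numbered 6 to 10 over the alternatives and 7 to 8 with 1 array left out, beside 8 reported, and list calls 132 to 150 and 131 to 143, beside 139. The difference of OGG1 between day 4 and duodenum, 0.08 and not called, was -1.03 with the mean of its probe sets (adjusted p = 0.0146, range over its alternatives 0.0146 to 0.986). Without ileum 3 the lipid absorption and fibroblast lists turned direction in colon against ileum and were not called (p = 0.886 and 0.47, with ranges over their alternatives of 1.71e-07 to 0.906 and 7.04e-06 to 0.47). Of 761 gene results by the naming rule, 94 values under an alternative changed sign while not called in either. Where not stated, the cause was not tested. Intensity near the floor limits dim genes, whose differences shrink towards 0.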

Other observations

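All values in this part were chosen after the data were seen. Some genes low in ileum were low on all 3 ileum arrays, and others, as CYP3A4, were not. AMPD1 was at 5.71, 5.26 and 5.14 on ileum 1, 2 and 3, S100G at the floor of 4.79 on each, and CES2 at 7.56, 6.33 and 12.31. The nucleoside transporter SLC28A1 was at 9.06 on ileum 3, within the duodenum range of 7.53 to 9.50, and SLC28A2 at 9.12, below its range of 10.02 to 12.26. The ileal bile acid carrier FABP6 was at 15.28 on ileum 3 and at 8.55 and 8.58 on ileum 1 and 2, and CA4, a carbonic anhydrase of the colon surface, at 11.81 on colon 3 and at 7.15 and 7.28 on colon 1 and 2. No test was run on these values.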
